A study of Mus musculus with 6 samples.

How the data were processed

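Poly(A)-selected RNA of mouse A2Lox.cre embryonic stem (ES) cells was sequenced on day 3 of embryoid body culture, per the labels' protocols. The 6 libraries formed 2 groups of 3, cells without doxycycline (replicates 2, 3 and 4) and cells given doxycycline for 24 hours from day 2 to express Flag-tagged Sp5 (replicates 1, 3 and 4). The labels do not say whether the replicates came from separate cultures, so the p-values below may measure only technical spread. Libraries were made with a TruSeq RNA kit from oligo-dT captured mRNA, and the protocol mentions no step that marks strand.

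The data were 1 table of 36699 gene rows in the layout of a Cuffdiff gene-level comparison. Per the submitters' processing notes, TopHat2 2.0.8, Bowtie, Picard, Cufflinks 2.0.2 and Cuffdiff were used with the mouse build mm9. The gene annotation, the library scaling and the filters are not given in the sources used here. Each row held 1 FPKM value (fragments scaled to transcript length and to the number of mapped fragments) for each group, as the authors deposited them. The authors combined the 3 libraries of a group into that value, so no SD or n accompanies it, and values per library were not analysed here. Depth is unknown, because the table holds no counts, and no counting interval or detection floor can be given. The log2 fold changes, p-values and q-values are those of the authors' own Cuffdiff test, per the file header. The design fixed beforehand allowed for values per library, for which a refit would have been the main test. With group values only, it named the authors' calls as the main result, and these were used.

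The table was checked before use. The log2 ratio of the group values equalled the deposited log2 fold change to within 1.31e-05 in the 18284 tested rows with both groups above 0. Benjamini-Hochberg adjustment of the deposited p-values over the 18537 rows with status OK gave the deposited q-values to within 1.79e-06. The authors' mark of significance matched status OK with q under 0.05 in every row, and that rule defined a call here. Of the other rows, 17612 had status NOTEST, with values up to 0.0678 FPKM, 431 had FAIL, 116 had HIDATA and 3 had LOWDATA, and none of these was tested. HIDATA is the status Cuffdiff gives to a locus with too many fragments. Of the 116 such rows, 79 were listed at 0 in both groups, including Gapdh, Eef1a1 and Rplp0, 29 at 0 in the plus group only and 8 at 0 in the minus group only. These zeros were read as failed estimates, not as levels. A q listed as 0 (516 called rows) is below the smallest value the file prints. The highest tested value was 913997 FPKM, and 9 tested rows, none of them called, had 10000 FPKM or more in a group.

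Rows naming more than 1 gene (454) were kept in the counts of calls and left out of gene lists. Rows that share a locus with another row (13133, of which 1321 were called) can share reads, because the protocol mentions no strand marking. Coordinates are in mm9 as the table gives them, written from 1. Starts were read as 0-based because gene spans then equalled GENCODE vM21 spans for 11704 of 27867 genes compared by length, against 316 when read as 1-based. No coordinate was taken from that annotation, which is of another build.

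Fold changes are ratios of the 2 deposited group values without a pseudocount, computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Gene lists, test design, alternatives and the rule for naming genes were fixed before the data were examined. Of 553 different genes in 28 lists, 518 had a row of their own and 465 were tested; 66 genes were in 2 or more lists. Sp5 was in no list. For each list, called members were counted in each direction at any level, so the counts include members under 1 FPKM in both groups. Called against uncalled members were compared with all other tested genes by Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 27 lists. Genes are not independent replicates, so this test describes these groups. It was not matched on level. The list's median log2(FPKM + 1) difference, with a pseudocount of 1 FPKM, was placed among 10000 random lists of the same size matched on mean level in 20 bins. Beside the count over all tested genes stands the count with p-values adjusted over the list alone. In simulated lists of 20 among the 18186 genes of this comparison, a shift of 0.5 on the log2 scale (spread 0.3) fell outside the central 95% of 1000 random lists in 100% of 100 lists, a shift of 0.25 in 84%, and no shift in 2%. The calls in these lists were drawn apart from the shift, at set rates of 70%, 50% and 23.3% of members. Fisher's p was under 0.05 in 99%, 77% and 8% of the same lists. These rates follow from the set call rates, not from the shifts. Simulated fold changes were independent between genes and had the same spread at every level. The simulation therefore gives no false rate for lists of genes that change together, and does not test the matching on level.

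Genes named are Sp5, the 12 largest rises and 12 largest falls among called genes with 1 FPKM or more in the higher group, and from each list up to 4 called members with the largest fold at that level, or more for 6 lists on Wnt targets, the primitive streak, presomitic mesoderm, naive pluripotency, definitive endoderm and Hox genes. A list with no called member gives its 2 most abundant ones. Some genes that the rule or a count picks out are not reported here. Genes named outside this rule are said to be so where they appear. Alternatives were q under 0.01 and under 0.10, a fold of at least 2, level minimums of 1 and 5 FPKM, a pseudocount of 0.1 FPKM, values rescaled to a median log2 fold change of 0, unmatched random lists, and genes of several lists left out. Rows sharing a locus or naming several genes were left out in alternatives added after seeing the data. Comparing settings by the percentile of a list's median, with the adjusted Fisher p as its call, leaving rows of several genes out of lists, and the window, distance and mitochondrial gene list of the closing tests were chosen after the data had been examined, and 1 window, 1 distance and 1 symbol-stem rule were tried. The bounds on the interval of the mitochondrial chaperone test, and the bound that decides the window test, were also set then, after their results were seen. A pseudocount of 1 FPKM was tried for the named genes as well and is not reported. Refits per library, replicates left out and a replicate block need values per library and were not run.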

Results

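Gene expression was measured in mouse A2Lox.cre ES cells, a line that carries a doxycycline-responsive site for inducible transgenes, after 3 days of differentiation as embryoid bodies. One group of 3 libraries came from untreated cells and the other group of 3 from cells given doxycycline for the last 24 hours to express Flag-tagged Sp5, a zinc-finger transcription factor and known target of Wnt signalling. The comparison asked which genes Sp5 regulates in differentiating ES cells. Expression is given as the authors' FPKM value of each group, which has no error of its own, and the spread between libraries enters only through the authors' test. Below, "rose" and "fell" are used of genes with q under 0.05 in the authors' deposited table, with values in cells with doxycycline set against those without. Cells given doxycycline without the transgene were not analysed here, so the drug and the transgene differ together between the groups.

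Sp5 itself stood at 0.769 FPKM without doxycycline and at 126 FPKM with it, a 164-fold rise (log2 fold change 7.36, q listed as 0 in the authors' deposited table). The row XLOC_016523 covers chromosome 2, positions 70312980 to 70315786 of mm9. Gene-level values do not separate the transgene from the endogenous gene. Its change was in the direction that the labels state.

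In the authors' deposited table, 4306 of 18537 tested genes changed, of which 1949 rose and 2357 fell. Rises were larger than falls. Among genes with a fold, 655 of 1948 that rose did so at least 2-fold (33.6%, 95% Wilson interval 31.6 to 35.8), against 411 of 2356 that fell (17.4%, 16.0 to 19.0). The median size was 0.69 on the log2 scale for rises and 0.49 for falls. The intervals treat genes as independent and hold no spread between libraries. The directions also differed in level, with 1414 of the 1949 rises and 2071 of the 2357 falls at 1 FPKM or more in the higher group. These shares and medians were not matched on level. At 1 FPKM or more in the higher group, 35 genes rose at least 8-fold and 3 fell as much. Many calls were small in size, with 34.9% of the rises and 51.3% of the falls under 0.5 on the log2 scale. With a minimum fold of 2, the balance turned to 656 higher and 412 lower.

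**Figure D1:**
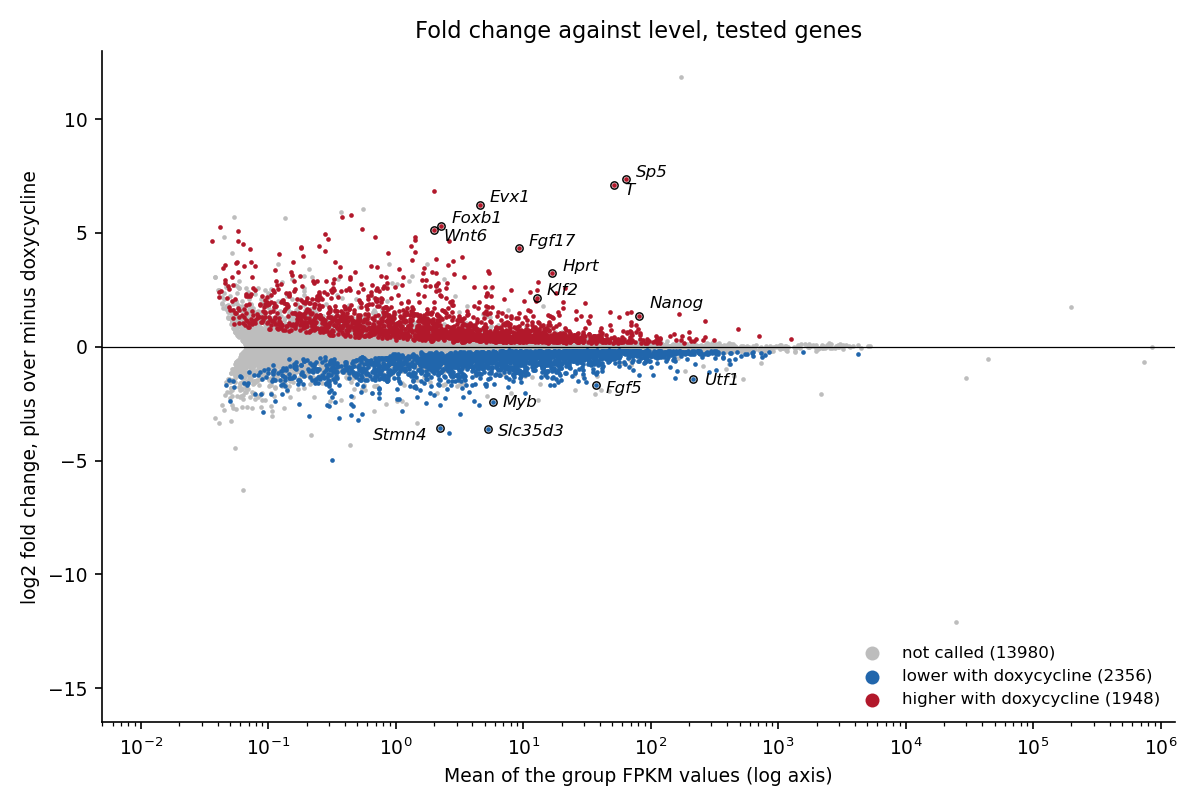
Each point is a tested gene with both groups above 0; the x axis is the mean of the 2 group FPKM values (log axis) and the y axis the log2 fold change, plus over minus doxycycline, with genes called higher in red, lower in blue and not called in grey. Sp5 (log2 fold change 7.36) and T (7.11) stand above the other called genes, while some uncalled points lie further out, and 1948 genes lie in red against 2356 in blue.

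The largest rise after Sp5 was that of T (Brachyury), the T-box factor of the primitive streak, from 0.745 to 103 FPKM (138-fold; chromosome 17, 8627288 to 8635361). Evx1, a homeobox gene of the posterior streak, rose from 0.119 to 9.01 FPKM (75.9-fold; chromosome 6, 52258383 to 52268372), and 5730457N03Rik, a transcript of the same locus, rose from 0.0353 to 3.99 FPKM. Foxb1, a forkhead factor, rose 39.9-fold to 4.43 FPKM together with B230323A14Rik at the same locus (36.2-fold, chromosome 9, 69605517 to 69678652); reads of each such pair may not be separable. Wnt6 rose 35.3-fold to 3.87 FPKM and Fgf17, a fibroblast growth factor, 20.2-fold to 17.5 FPKM. The other genes among the 12 largest rises were the neuropeptide gene Tac2 (28.5-fold), the zinc-finger repressor Scrt1 (28.4-fold), the kisspeptin receptor Kiss1r (25.6-fold), the lipoxygenase gene Alox15 (24.7-fold) and Prr18 (21.8-fold), which neighbours T on chromosome 17. All 12 had q listed as 0 in the authors' deposited table except Kiss1r (q = 0.00364) and Prr18 (q = 1.18e-12).

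Among falls, Slc35d3, a solute carrier family member, went from 9.73 to 0.792 FPKM (12.3-fold lower; chromosome 10, 19567723 to 19571265). Stmn4, a stathmin of neurons, fell from 4.11 to 0.341 FPKM. The pseudogene H3f3a-ps2 was 13.7-fold lower, a value that is uncertain because its reads can be shared with its parent gene. Sertad4 was 7.74-fold lower, the cytokine gene Il10 6.97-fold and Crym (mu-crystallin) 5.92-fold. Myb, a transcription factor of progenitor cells, fell from 9.70 to 1.80 FPKM (5.39-fold), and the phospholipase gene Plcd1 5.19-fold. Sned1 (5.61-fold) and Sez6 (4.93-fold) fell too, as did the predicted genes Gm4294 (5.91-fold) and Gm13253 (4.87-fold). In the authors' deposited table, q was listed as 0 for these 12 except Sned1 (q = 0.00749) and Gm13253 (q = 1.44e-05).

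Genes of the primitive streak and early mesendoderm rose as a group. Of 20 tested members, 16 rose, 1 fell and 3 were not called in the authors' deposited table (19 changed when adjusted over the list alone). Beside T, Evx1 and Fgf17, these were Wnt3a (0.0172 to 0.344 FPKM, named after its values were seen), the mesoderm factor Mesp1 (0.0948 to 1.64 FPKM, 17.3-fold), the ligand Wnt3 (0.555 to 5.14 FPKM, 9.25-fold), Wnt5b (6.32-fold), Lefty2 (2.98-fold), Lefty1 (34.8 to 95.9 FPKM, 2.75-fold), Mixl1 (2.74-fold), Eomes (10.4 to 27.8 FPKM, 2.67-fold), Snai1 (2.45-fold), Nodal (15.9 to 36.5 FPKM, 2.30-fold), Gsc (2.01-fold), Fgf8 (1.67-fold) and Tdgf1 (1.46-fold). Cer1, which encodes a secreted Nodal and BMP antagonist of anterior endoderm, fell from 7.67 to 2.90 FPKM (2.64-fold). The share of called members, 85.0% against 23.3% of other tested genes, gave an adjusted p of 1.3e-07 (Fisher's exact test), and the median of 1.04 (log2) lay above all 10000 random lists. An adjusted p under 0.05 in Fisher's exact test was reached by 18 of the 27 tested lists. That test was not matched on level, so passing it does not single out a list. With the 17 members that other lists share left out, the adjusted p was 0.178 over the 3 that remained, whose median lay at the 99.9th percentile.

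**Figure D2:**
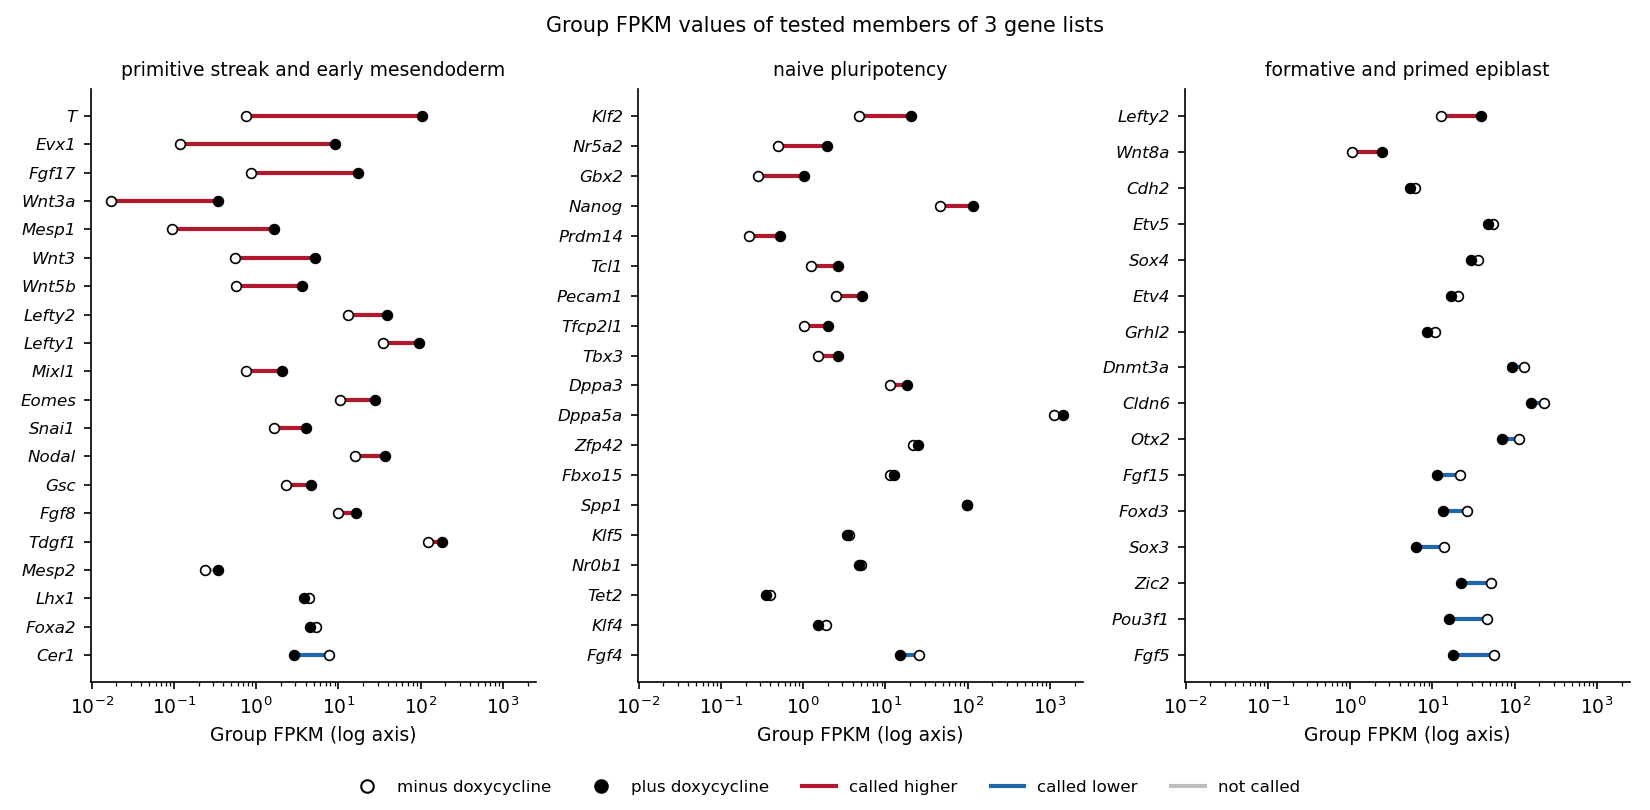
Group FPKM (log axis) of each tested member of 3 gene lists, without doxycycline (open circles) and with it (filled circles), joined by a red line where called higher, blue where called lower and grey where not called; each circle is 1 group value and has no error bar. Most primitive streak and naive pluripotency genes shift to the right (16 of 20 and 12 of 19), and most formative epiblast genes to the left (12 of 16).

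Wnt/beta-catenin target genes rose as well, with 15 higher, 1 lower and 10 not called of 26 tested in the authors' deposited table (17 changed when adjusted over the list alone). Axin2, the feedback inhibitor of the pathway, rose from 1.59 to 9.77 FPKM (6.13-fold), Tnfrsf19 from 1.16 to 7.12 FPKM (6.14-fold) and the caudal homeobox gene Cdx2 from 0.262 to 3.85 FPKM (14.7-fold). The secreted antagonists Notum (3.25-fold) and Dkk1 (2.59 to 7.23 FPKM, 2.79-fold), Apcdd1 (2.54-fold), Nkd1 (2.32-fold) and Bambi (1.27-fold) also rose, and the cyclin gene Ccnd1 fell 1.16-fold (q = 0.0203 in the authors' deposited table). Dkk4, Cdx1, Cdx4, Lgr5 and Zfp703, named after their values were seen, rose but stayed under 1 FPKM in both groups. Lef1 (9.96 and 10.6 FPKM), Tcf7 (26.4 and 22.8 FPKM), Myc (13.9 and 13.6 FPKM) and Sp8 (0.367 and 0.44 FPKM), named after their values were seen, were not called. The adjusted p of the list was 0.000115 (Fisher's exact test) and its median lay at the 99.98th percentile of random lists. Without genes of other lists the adjusted p was 0.0556 and the percentile 93.0.

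Components of Wnt signalling changed in both directions. In the authors' deposited table, 21 of 47 tested ligands, receptors and antagonists rose, 11 fell and 15 were not called (34 changed when adjusted over the list alone; adjusted p = 2.48e-09, Fisher's exact test). Wnt6 and Wnt3 rose as given above, the receptor Fzd10 rose from 0.965 to 9.62 FPKM (9.96-fold) and the secreted antagonist Frzb from 0.392 to 3.74 FPKM (9.52-fold). Wnt3a, Wnt9b, Wnt10a, Dkk3, Dkk4, Rspo3, Lgr5 and Lgr6, named after their values were seen, rose but stayed under 1 FPKM in both groups. Among those that fell, named after their values were seen, Kremen1 went from 3.02 to 1.36 FPKM and the receptor Fzd7 from 43.5 to 28.7 FPKM. The median lay at the 99.99th percentile of random lists, and at 33.1 when genes of several lists were left out, so the direction of this list rested on shared members.

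In the list of neuromesodermal progenitors and presomitic mesoderm, 15 of 26 tested members rose, 2 fell and 9 were not called in the authors' deposited table (19 changed when adjusted over the list alone). Lfng, a modifier of Notch signalling, rose from 2.32 to 7.97 FPKM (3.43-fold), Fgf18 6.23-fold, Wnt5a 2.70-fold and the Notch ligand gene Dll3 1.64-fold, beside T, Evx1, Fgf17 and Cdx2. The other rises, named after their values were seen, stayed under 1 FPKM in both groups. They were those of Cdx1, Cdx4, Wnt3a, Hoxb1, Pax3, Aldh1a2 and Rspo3. Fgf4 fell 1.66-fold and Cyp26a1, a retinoic acid-degrading enzyme, 1.19-fold. Tbx6 and Msgn1, which mark presomitic mesoderm and were named after their values were seen, stood at 0.363 and 0.553 FPKM and at 0.0166 and 0.1 FPKM, without and with doxycycline, and neither was called (q = 0.105 and q = 0.257 in the authors' deposited table). Adjusted p for the list was 2.7e-05 (Fisher's exact test) with a median above all 10000 random lists. With the 19 shared members left out it was 0.258, with the median of the rest at the 97.9th percentile.

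Hox genes were low in both groups. Of 17 tested, 4 rose, 1 fell and 12 were not called in the authors' deposited table (5 changed when adjusted over the list alone; adjusted p = 0.613, Fisher's exact test; median at the 81.2th percentile). None of the called members reached 1 FPKM, and those named were chosen after their values were seen. Hoxb9 went from 0.121 to 0.735 FPKM, Hoxb1 from 0.0225 to 0.354 and Hoxb2 from 0.0464 to 0.136, while Hoxd13 went from 0.411 to 0.248 FPKM.

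The Nodal and BMP pathway list had 16 of 27 tested members higher, 3 lower and 8 not called in the authors' deposited table (19 changed when adjusted over the list alone). Msx1 and Msx2, homeobox genes that respond to BMP signalling, rose 5.68-fold (2.41 to 13.7 FPKM) and 5.71-fold. The ligand gene Bmp4 rose from 1.83 to 8.46 FPKM (4.62-fold) and the BMP antagonist gene Nog 6.55-fold to 1.13 FPKM. Adjusted p was 1.97e-06 (Fisher's exact test), and the median of 0.56 (log2) lay above all 10000 random lists.

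Pluripotency genes moved apart by class. Of 19 tested naive pluripotency genes, 12 rose, 1 fell and 6 were not called in the authors' deposited table (14 changed when adjusted over the list alone). Klf2 rose from 4.72 to 20.7 FPKM (4.39-fold), Nr5a2 3.98-fold, Gbx2 3.65-fold and Nanog, a core factor of the naive state, from 46.0 to 117 FPKM (2.54-fold). Smaller rises were those of Tcl1 (2.13-fold), Pecam1 (2.06-fold), Tfcp2l1 (1.97-fold), Tbx3 (1.72-fold), Dppa3 (1.62-fold), Dppa5a (1.28-fold) and Zfp42 (1.15-fold), and Fgf4 fell. Named after their values were seen, Klf4 (1.88 and 1.50 FPKM), Klf5, Nr0b1, Fbxo15, Tet2 and Spp1 were not called. Esrrb (3.44 and 5.58 FPKM), also named after its values were seen, had status FAIL and was not tested. In the formative and primed epiblast list, 12 of 16 tested members fell, 2 rose and 2 were not called in the authors' deposited table (16 changed when adjusted over the list alone). Fgf5, a marker of the primed epiblast, fell from 56.5 to 17.8 FPKM (3.17-fold) and the POU factor Pou3f1 from 45.9 to 15.8 FPKM (2.90-fold), whereas Lefty2 and Wnt8a (2.32-fold) rose. Adjusted p was 0.000115 for the naive list and 9.31e-07 for the formative list (Fisher's exact test), with medians above and below all 10000 random lists. The core pluripotency list was mixed, with 1 of 11 tested members higher, 4 lower and 6 not called in the authors' deposited table (5 changed when adjusted over the list alone; adjusted p = 0.168, Fisher's exact test; median at the 8.35th percentile). There Utf1 fell from 314 to 119 FPKM (2.64-fold), Dppa4 1.23-fold and Lin28a 1.21-fold, and Tdgf1 rose. Pou5f1 (999 and 1058 FPKM) and Sox2 (60.8 and 60.6 FPKM), named after their values were seen, were not called.

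**Figure D3:**
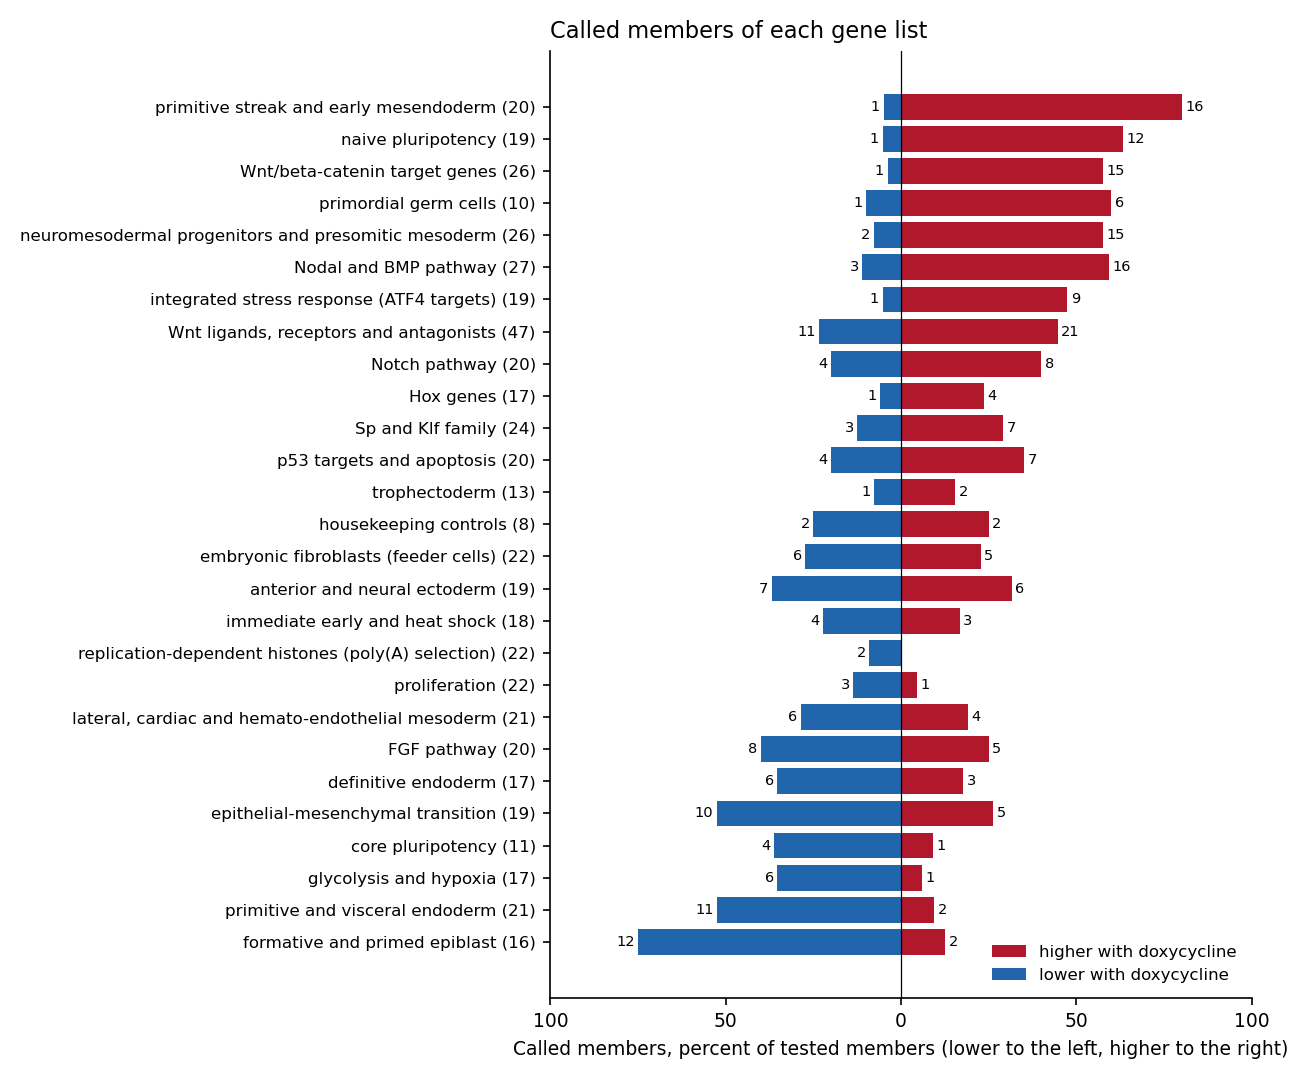
Called members of the 27 tested gene lists as a percent of each list's tested members (the number in parentheses), with members lower with doxycycline in blue to the left, those higher in red to the right, and counts at the bar ends. Primitive streak genes have 16 higher and 1 lower of 20, formative and primed epiblast genes 2 higher and 12 lower of 16.

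Genes of primitive and visceral endoderm fell. In the authors' deposited table, 11 of 21 tested members fell, 2 rose and 8 were not called (13 changed when adjusted over the list alone; adjusted p = 0.000434, Fisher's exact test), and the median of -0.27 (log2) lay below all 10000 random lists. Sox7 fell 1.71-fold, the laminin gene Lama1 1.69-fold (11.8 to 6.98 FPKM), Gata6, a primitive endoderm factor, 1.61-fold (4.43 to 2.76 FPKM) and Afp (alpha-fetoprotein) 1.60-fold. Definitive endoderm genes were mixed, with 3 of 17 higher, 6 lower and 8 not called in the authors' deposited table (9 changed when adjusted over the list alone; adjusted p = 0.013, Fisher's exact test; median at the 18.7th percentile). The peptide hormone gene Pyy rose 10.9-fold to 3.04 FPKM and Krt19 1.39-fold. Besides Cer1, Krt18 fell 2.01-fold (96.4 to 48.0 FPKM), Krt8 1.60-fold, Otx2 1.60-fold (112 to 70.0 FPKM), Cldn6 1.45-fold and Spink3 1.27-fold. Foxa2 (5.34 and 4.47 FPKM) and Sox17 (3.13 FPKM in both groups), named after their values were seen, were not called. Without genes of other lists, the definitive endoderm median moved to the 78.9th percentile and the adjusted p to 0.50.

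Anterior and neural ectoderm genes went both ways, with 6 of 19 tested members higher, 7 lower and 6 not called in the authors' deposited table (14 changed when adjusted over the list alone; adjusted p = 0.000115, Fisher's exact test). The Iroquois homeobox gene Irx3 rose 12.1-fold to 4.77 FPKM and Gbx2 3.65-fold. The intermediate filament gene Nes fell 2.63-fold (13.8 to 5.24 FPKM) and the eye and forebrain factor Pax6 4.04-fold (1.05 to 0.26 FPKM). The list's median of -0.14 (log2) lay at the 0.09th percentile. Among genes of lateral, cardiac and hemato-endothelial mesoderm, 4 of 21 rose, 6 fell and 11 were not called in the authors' deposited table (12 changed when adjusted over the list alone; adjusted p = 0.0247, Fisher's exact test; median at the 5.99th percentile). Etv2, a factor of blood and endothelial specification, fell from 5.15 to 1.47 FPKM (3.51-fold), while Mesp1, Bmp4 and Pecam1 rose. The other called members were named after their values were seen. Of these, Myl7 (7.83 to 4.77 FPKM), Tal1 (0.849 to 0.26 FPKM), Kdr, Cdh5 and Hba-x fell and Nkx2-5 rose, and only Myl7 reached 1 FPKM. Among members at 1 FPKM or more this list's median lay at the 56.4th percentile and the adjusted p was 0.0642, and without genes of other lists they were 0.11 and 0.121. In the trophectoderm list, Cdx2 and Tfap2a (13.9-fold, to 2.50 FPKM) rose, Krt7 fell 2.17-fold and the other 10 of 13 were not called in the authors' deposited table (5 changed when adjusted over the list alone; adjusted p = 1, Fisher's exact test; median at the 75.6th percentile, and at 47.4 without genes of other lists).

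Of 24 tested members of the Sp and Klf family, to which Sp5 belongs, 7 rose, 3 fell and 14 were not called in the authors' deposited table (11 changed when adjusted over the list alone; adjusted p = 0.0705, Fisher's exact test; median at the 52.2th percentile). Besides Klf2, Klf12 rose 1.45-fold and Klf3 1.34-fold, and Klf6 fell 1.47-fold. With members at 1 FPKM or more the adjusted p was 0.0468.

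Markers of other cells and of RNA handling were examined beside these groups. The ES cells had been grown on mouse embryonic fibroblasts, and of 22 tested fibroblast genes 5 rose, 6 fell and 11 were not called in the authors' deposited table (12 changed when adjusted over the list alone; adjusted p = 0.0137, Fisher's exact test; median at the 7.91th percentile). With members at 1 FPKM or more, this fibroblast list's median lay at the 1.24th percentile (adjusted p = 0.0278, Fisher's exact test). Col1a1 rose from 1.11 to 4.43 FPKM (3.99-fold) and Col5a1 1.86-fold, whereas Acta2 fell from 18.9 to 9.92 FPKM (1.90-fold) and Thbs1 2.15-fold. Most mRNAs of replication-dependent histone genes lack a poly(A) tail. Of 22 tested, 2 fell, none rose and 20 were not called in the authors' deposited table (2 changed when adjusted over the list alone). The list's adjusted p was 0.165 (Fisher's exact test), with the median at the 10.4th percentile, and Hist1h1c was 1.33-fold lower. Immediate early and heat shock genes had 3 of 18 higher, 4 lower and 11 not called in the authors' deposited table (8 changed when adjusted over the list alone; adjusted p = 0.178, Fisher's exact test; median at the 70.8th percentile). Egr1 fell 2.85-fold, Dusp1 1.59-fold and Jund 1.46-fold, and Ier3 rose 1.50-fold. With members at 1 FPKM or more, this median lay at the 7.96th percentile. Proliferation genes had 1 of 22 higher, 3 lower and 18 not called in the authors' deposited table (4 changed when adjusted over the list alone; adjusted p = 0.832, Fisher's exact test; median at the 30.0th percentile), the called ones being Ccnb2 (1.18-fold higher), Ccne1 (1.32-fold lower), Ccna2 (1.16-fold lower) and Bub1b (1.14-fold lower). Among housekeeping controls, 2 of 8 tested rose, 2 fell and 4 were not called in the authors' deposited table (4 changed when adjusted over the list alone; adjusted p = 0.118, Fisher's exact test; median at the 73.7th percentile, and at 38.5 among random lists not matched on level). Hprt rose from 3.24 to 30.5 FPKM (9.41-fold; chromosome X, 50341314 to 50374836) and B2m 1.32-fold, while Actb fell 1.21-fold. The mitochondrially encoded genes mt-Cytb and mt-Nd6 were listed at 0 with status HIDATA and were not tested.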

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

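Rows outside the authors' tested set were examined for values at 1 FPKM or more and at least 2-fold higher with doxycycline, a rule chosen after seeing the data. It picked out 13 rows, 8 with status FAIL and 5 with HIDATA, of which 12 are given, while 21 untested rows met the mirror rule, so neither direction is a called change. Tgm2, the transglutaminase gene, stood at 0.919 FPKM without and 9.06 FPKM with doxycycline, and Gm20412, a row of the same locus, at 1.09 and 9.29 FPKM. Mdfic stood at 1.17 and 4.59 FPKM, AU015836 at 0.95 and 2.04 FPKM, and Syne1 at 0.375 and 1.22 FPKM. Dnmt3b, Ldha and the predicted genes Gm14760, Gm12671 and Gm13394 were listed at 0 without doxycycline and at 273, 1263, 3.65, 2.79 and 1.17 FPKM with it, all with status HIDATA. The listed zeros of these rows are failed estimates for the group, since Gapdh, Eef1a1 and Rplp0 are listed at 0 in both groups with the same status. The rows of 2 U6 copies were listed at 0 without and at 1.14 and 1.13 FPKM with doxycycline. Outlying libraries and differences between further groups could not be looked for in group values.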

How the results depend on the processing

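The count of called genes kept within 1.5 times of the main values (4306 in all, 1949 higher, 2357 lower) at q under 0.01 (3170, 1430 and 1740), at q under 0.10 (5008, 2252 and 2756), with 1 FPKM or more in the higher group (3485, 1414 and 2071), and, in alternatives added after seeing the data, without rows sharing a locus (2985, 1356 and 1629) or naming several genes (4247, 1928 and 2319). It moved further with a fold of at least 2 (1068, 656 and 412) and with 5 FPKM or more in the higher group (2319, 829 and 1490), both of which leave fewer genes by construction; the share of rises was 45.3% in the main count, 61.4% with the fold minimum and 35.7% at 5 FPKM. The median log2 fold change of 7731 genes at 5 FPKM or more in both groups was -0.05; rescaling to 0 shifts all genes alike while the authors' q stay fixed, so its unchanged counts say nothing about scaling. At q under 0.01, rises of at least 2-fold made up 39.1% and falls 20.3%, with median sizes of 0.79 and 0.57 on the log2 scale, since that threshold removes small changes. Of 134 named genes with a fold, 4 calls (Ccnd1, Zfp42, Ccna2 and Bub1b) were lost at q under 0.01; the settings run on single genes could hardly turn a direction.

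For the gene lists, values below are percentiles of the list median. No list median crossed the middle with a pseudocount of 0.1 FPKM. With members at 1 FPKM or more, the lateral, cardiac and hemato-endothelial list moved to 56.4 and the immediate early list to 7.96, and the Sp and Klf list passed the threshold at 69.4. Unmatched random lists put the housekeeping list at 38.5. At q under 0.01 the core pluripotency list (8.35) and the housekeeping list (73.7) passed the threshold. Leaving out genes of several lists, which leaves fewer genes to test, ended the calls of the Wnt target (93.0), primitive streak (99.9), presomitic mesoderm (97.9) and lateral mesoderm (0.11) lists without turning their direction, ended those of the definitive endoderm (78.9, adjusted p = 0.50) and FGF (50.1, adjusted p = 0.0719) lists and moved both across the middle, as it did the trophectoderm (47.4) and Wnt component (33.1) lists (Fisher's exact test); apart from the smaller lists, the cause was not tested. No paired analysis was possible because the table holds 1 value per group, although replicate numbers 3 and 4 occur in both groups. For the same reason no replicate could be left out, no other split of the libraries could be counted, and the grouping of libraries stays unexamined beyond the authors' own test. Depth is unknown, so it cannot be said which uncalled low genes were limited by it.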

Other observations

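Further lists fixed before the data were examined are given here. Of 19 tested genes of the epithelial-mesenchymal transition list, 10 fell, 5 rose and 4 were not called in the authors' deposited table (17 changed when adjusted over the list alone; adjusted p = 2.57e-06, Fisher's exact test), and the median of -0.24 (log2) lay below all 10000 random lists. Epithelial Krt18 fell 2.01-fold, while the repressor gene Snai1 rose 2.45-fold and the matrix metalloproteinase gene Mmp2 2.26-fold (6.62 to 14.9 FPKM), and mesenchymal Twist1 fell 1.66-fold. The list mixes epithelial and mesenchymal markers, so its median gives no direction of such a transition. Named after their values were seen, epithelial Cdh1, Epcam, Cldn3, Cldn6, Cldn7, Ocln and Krt8 fell, mesenchymal Zeb1, Zeb2 and Prrx1 rose, and mesenchymal Vim fell. In the FGF list, 5 of 20 rose, 8 fell and 7 were not called in the authors' deposited table (14 changed when adjusted over the list alone; adjusted p = 0.000231, Fisher's exact test; median at the 3.51th percentile), and the ligand genes split, Fgf17 and Fgf18 rising 20.2-fold and 6.23-fold while Fgf5 fell 3.17-fold and Fgf15 1.89-fold (21.6 to 11.5 FPKM). Without genes of other lists, the FGF list was no longer called (adjusted p = 0.0719, Fisher's exact test) and its median lay at the 50.1th percentile. The Notch list had 8 of 20 higher, 4 lower and 8 not called in the authors' deposited table (12 changed when adjusted over the list alone; adjusted p = 0.00107, Fisher's exact test; median at the 97.6th percentile), with the repressor gene Hes3 rising 17.9-fold to 2.66 FPKM, Lfng 3.43-fold and Maml3 1.86-fold, and Hey1 falling 1.87-fold.

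Primordial germ cell genes had 6 of 10 higher, 1 lower and 3 not called in the authors' deposited table (8 changed when adjusted over the list alone; adjusted p = 0.00441, Fisher's exact test; median at the 99.97th percentile), among them Nanos3 (3.91-fold, to 1.23 FPKM), Ifitm1 (88.8 to 243 FPKM, 2.74-fold), Dppa3 (1.62-fold) and Prdm1 (1.57-fold). Glycolysis and hypoxia genes had 1 of 17 higher, 6 lower and 10 not called in the authors' deposited table (8 changed when adjusted over the list alone; adjusted p = 0.118, Fisher's exact test; median at the 0.205th percentile). The glucose transporter gene Slc2a1 fell from 283 to 166 FPKM (1.70-fold), Bnip3 1.63-fold and Pfkl 1.36-fold, and Slc2a3 rose 1.40-fold. Of 20 p53 target and apoptosis genes, 7 rose, 4 fell and 9 were not called in the authors' deposited table (11 changed when adjusted over the list alone; adjusted p = 0.00441, Fisher's exact test; median at the 98.2th percentile), with the cell cycle inhibitor gene Cdkn1a rising from 16.1 to 40.8 FPKM (2.53-fold) and Perp 1.49-fold, and Pmaip1 and Gadd45a falling 1.56-fold and 1.50-fold. With members at 1 FPKM or more, the p53 list's median lay at the 93.4th percentile, and without genes of other lists at the 91.8th. Mdm2, Bax and Bbc3 of this list, named after their values were seen, were not called. A large fold without a call, named after its value was seen, was that of Nkx1-2, a gene of neuromesodermal progenitors, from 0.264 to 3.26 FPKM (12.3-fold, q = 0.43 in the authors' deposited table), and Ghrh went from 0.0164 to 1.10 FPKM (q = 0.0534). The row of Nkx1-2 covers a long locus (chromosome 7, 137305965 to 140316037), so its value may hold reads of other genes.

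The 3 patterns below were picked from 5 noticed in the data; the others were the zeros of untested abundant genes and a drift of the median log2 fold change from 0.05 for genes under 1 FPKM to -0.08 at 100 FPKM or more. The tests of a regional gain, of other windows, of the cassette and of the drug were chosen after the values they use had been seen. The other tests were set before their result was seen, though values of single genes they rest on (near T and Evx1) had been. The bounds on the interval of the mitochondrial genes were set after. The first pattern is Hprt, which rose 9.41-fold while most genes around it did not: of 14 other tested genes at 1 FPKM or more within 1 Mb, 8 fell and 3 rose, including, named after their values were seen, Ccdc160 (3.59-fold lower), Gpc3 (1.79-fold lower), Gpc4 (1.75-fold lower), Fam122b (1.72-fold lower) and Phf6 (1.38-fold lower), and Cxx1c (4.42-fold higher). Their median log2 fold change was -0.50 (bootstrap 95% interval -0.80 to 0.18), which argues against a gain of transcription or copy number across the region. As low a median was found in 0.0799% of 11260 overlapping windows, 9 in all with this one included, and in 3 of 382 on chromosome X, but this window was picked after its values were seen and its interval includes the median of all windows (-0.05), so a fall of the region is not established and the spread of windows stays open. A candidate explanation for Hprt itself (log2 fold change 3.23) is transcription from the inducible cassette, which in this line is known to lie beside Hprt; gene-level values cannot tell cassette reads from those of Sp5 or Hprt, so this stays open, as does an effect of Sp5.

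The second pattern is a rise of ATF4 target genes of the integrated stress response, with 9 of 19 tested members higher, 1 lower and 9 not called in the authors' deposited table (10 changed when adjusted over the list alone; adjusted p = 0.00953, Fisher's exact test) and the median at the 99.99th percentile of random lists. Asns rose 1.52-fold (51.9 to 78.9 FPKM), Vldlr 1.56-fold, Sesn2 1.49-fold and Nupr1 1.48-fold, while Atf4 (129 and 117 FPKM), Ddit3 (7.71 and 8.23 FPKM) and Trib3 (6.52 and 6.84 FPKM), named after their values were seen, were not called. Doxycycline inhibits mitochondrial translation, so the drug may contribute apart from Flag-Sp5; the 2 cannot be told apart, because they change together in these groups. A mitochondrial protein-folding response was tested on 12 chaperone and protease genes, of which none rose and 3 fell in the authors' deposited table, with a median of -0.13 (log2, bootstrap 95% interval -0.17 to -0.05) at the 10.2th percentile of random lists. Before the result was seen, the rule asked for a median above the random lists' central 95% if this response were the cause. A median below their middle was to count against it. By that rule the values argue against a raised response in these 12 genes. The whole interval also lay below 0.02, the upper bound of the central 95%. A stricter bound was the random lists' median of -0.07, which the interval reaches above, and by it the question would stay open. The bounds on the interval were set after the result was seen.

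The third pattern is that neighbouring genes rose together. Among 11970 tested genes at 1 FPKM or more, 297 rose at least 2-fold, and 25 pairs of them lay within 50 kb of each other, against a mean of 7.99 in 10000 permutations matched on level (permutation p = 0.0001, the smallest they can give). Examples are T with Prr18, Evx1 with 5730457N03Rik, Foxb1 with B230323A14Rik, Fgf17 with Epb4.9 (named after its value was seen), and Lefty1 with Lefty2. With overlapping loci left out, 19 pairs remained (95% of permutations between 2 and 12, permutation p = 0.0002), and without pairs of 1 symbol stem as well 17 remained (permutation p = 0.0009). Shared reads within overlapping pairs or gene families are therefore not the whole account. The pairs are not independent, since Prr18 and Gm16702 (named after its value was seen) overlap and each still counts as a pair with T. Pairs that fell together were not counted. Shared regulation of neighbours and transcripts that run on from an induced gene into the next were not tested.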
